A study of Homo sapiens with 165 samples.

How the data were processed

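Messenger RNA was measured in 165 skin biopsies of 41 patients with atopic dermatitis, with 1 library per biopsy and no pooling. Per the labels' protocols, total RNA was extracted with a column kit and stranded, poly(A)-selected libraries were sequenced as single-end reads on an Illumina instrument. Per the submitters' processing notes, FastQC, MultiQC, STAR, featureCounts and limma were used, in versions not given there, with genome build GRCh38. The gene annotation is not given in the sources used here.

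The authors deposited 1 table of log2 values, with 23582 rows named by gene symbol and 165 columns, all of which were used. The deposited log2 values are log2 counts per 1e6 reads (log2 CPM) in the form that limma's voom function writes, with 0.5 added to each count and no scaling between libraries beyond the library total. This was found from the values: 100% of them gave whole reads within 0.05 of a read (largest distance 0.0057) when the transformation was undone. The recovered totals, which count reads assigned to the rows of the table, ranged from 17.28 to 47.14 M with a median of 34.9 M. A library had 0 reads in a median of 8.8% of rows. Low-count genes are the least precise, so genes near the floor are named with their reads or given as detection only. A log2 fold change of such a gene rests on the added 0.5 and understates the change.

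The table holds 27 date-like row names, which spreadsheet software makes from gene symbols and which were not named here, 2 duplicated names and no mitochondrial rows. Of 338 genes in 26 lists fixed before the data were examined, 334 were found, some under older symbols. The lists cover keratinocyte responses, T helper axes, barrier and lipid genes, cell types that a skin biopsy can hold, and tissue handling. Some genes are in 2 lists (AWAT1, AWAT2, FADS2 and GAL in the lipid and sebaceous lists, CIDEA in the adipocyte and sebaceous lists), and many cell type markers are also expressed by other skin cells, so a list describes bulk tissue and names no cell. Gene positions came from GENCODE release 29 on GRCh38. Reads of near-identical copies (DEFB4A and DEFB4B, the KRT6 genes, KRT16 and its pseudogenes, the alpha-globin genes) are uncertain, since how the counting treated them is not given in the sources used here.

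Groups were arm, tissue and visit as the labels give them, 10 in all. The patient number of the labels paired the biopsies. In a check of the pairing, 276 pairs of libraries of the same patient had a mean correlation of deviations from their group means of 0.26 against -0.01 for different patients, 88.4% of the pairs lay above 0.1, and 126 libraries were closest to another library of their own patient. No 2 libraries correlated above 0.9823, so none was treated as a copy. In a check for mixed-up samples, marker genes whose detection does not vary within a person put each library in 1 of 2 classes. Of 165 libraries, 3 did not match the class of their patient's other libraries. Marker reads of both classes, taken as reads of more than 1 donor, were held by 4, which makes 4 libraries in all. They stayed in the analysis and were left out in an alternative. This check and its thresholds were chosen after seeing the data. It cannot see swaps between patients of the same class or between biopsies of 1 patient.

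Differential expression was computed with limma 3.58.1 (R 4.3.3, statmod 1.5.0) on the deposited values, in 1 fit of all libraries with a mean per group, the patient as a random block (estimated correlation 0.278), and moderated variances with a trend and robust settings. P values were adjusted by the Benjamini-Hochberg method over 23582 rows, and a gene was called at an adjusted p under 0.05. A filter that keeps genes with at least 1 read in 8 libraries removed 0 rows. The comparison of lesional with nonlesional skin at baseline weighted the arms by the ratio of the randomization. All tests were two-sided. The fit was tested on simulated reads for the same patients, genes and depths with 50 genes changed at each of 4 sizes. At baseline it recovered 88% of genes changed 1.5-fold, 94% of those changed 2-fold and all of those changed 4-fold or 8-fold. It made 10 false calls among 23582. The changed genes were drawn from those with a mean above 0 log2 CPM. Variation was drawn gene by gene, with no shift shared by the genes of a library.

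A list score was the mean log2 value of a list's genes in a library. Changes within patients were tested by sign-flip permutation (exact up to 22 pairs, otherwise 100000 resamples) and differences between arms by permuting the arm over patients (exact where an arm had fewer than 10 patients, otherwise 100000 resamples), with Benjamini-Hochberg adjustment over the 26 lists of each comparison. Intervals are 95% percentile bootstrap intervals from 10000 draws of patients. Lists were also tested against all other genes with limma's camera test on the moderated statistics, with a preset correlation of 0.01 and with the correlation estimated for each list. The lesional score used the 932 genes called at baseline with at least a 2-fold change. Scores were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.

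The genes named were set by rules fixed before the data were examined. At baseline these were the 10 genes with the highest and the 10 with the lowest log2 fold change among those called with the same sign in at least 75% of patient pairs. In each other comparison they were up to 10 called genes each way by size, or, where none was called, the 3 each way with the smallest p. In the main comparisons the rule also takes a fixed panel and the ends of the lists as examples. Genes that reflect a person's sex or a common gene deletion, HLA genes and immunoglobulin or T cell receptor segments were not named. IL17A and IL17F were added as the drug's target and its relative. Some genes that these rules take are not reported here.

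Alternatives fixed beforehand were no patient block, the patient as a fixed effect, the 25% of genes with the lowest means left out, quantile normalization, sequencing lane or sample-sheet set (3 sets, inferred from the numbering in the labels) as a factor, library weights (array weights), a 2-fold limit, only the 22 patients with all 5 biopsies, z-scored lists, removal of set means, both camera settings, lesional genes chosen in one part of the patients and scored in the rest, no fold limit, and the Th2 list as baseline measure. Alternatives chosen after seeing the data were trimmed-mean scaling, the library median as a covariate, voom weights from the recovered reads, and leaving out 6 libraries of outlying median or the 4 of doubtful identity, as were the contrasts of each arm alone at baseline, of the arms in nonlesional skin at baseline, and of the lesional against nonlesional difference between the arms, and the score tests of lesional skin between the arms at baseline and of the change of nonlesional skin. Choices that need a table of counts or a linear scale did not apply. Clinical outcomes and epidermal thickness were not used here.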

Results

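Skin biopsies were profiled by mRNA sequencing in a randomized, double-blind trial of secukinumab, an antibody that neutralizes the cytokine IL-17A, against placebo in adults with moderate-to-severe atopic dermatitis. Secukinumab was given under the skin at 300 mg, and the question put to the biopsies was whether blocking IL-17A moved lesional skin towards nonlesional skin. The 165 libraries came from 41 patients, of whom 27 received secukinumab and 14 placebo. Lesional (LS) skin was sampled at baseline (BL), week 4 (W4) and week 16 (W16), and nonlesional (NL) skin at baseline and week 16. The secukinumab arm gave 26 LS BL, 22 LS W4, 18 LS W16, 27 NL BL and 16 NL W16 libraries, and the placebo arm gave 14, 13, 9, 12 and 8 libraries in the same order. Values were log2 CPM (counts per 1e6 reads) for 23582 gene rows. Reads assigned to genes ranged from 17.28 to 47.14 M per library (1 M being 1e6), with a median of 34.9 M, and between 20321 and 22362 rows had at least 1 read. Fold changes below are on the log2 scale with their standard error (SE), from limma with the patient as a random block and Benjamini-Hochberg adjustment over all rows.

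Before treatment, lesional skin differed from nonlesional skin of the same patients across keratinocyte, immune and appendage genes. Among the largest rises, KRT6C, a keratin of thickened epidermis, was 11.8-fold higher (log2 3.56, SE 0.54, limma adjusted p = 3.2e-08). IL36A, an epidermal cytokine of the IL-1 family, was 11.5-fold higher (log2 3.53, SE 0.43, limma adjusted p = 4.6e-11). IL36A was higher in the lesional biopsy in 36 of the 38 patients with both biopsies, although its median was only 64.5 reads in LS and 2 reads in NL libraries. Among the genes with the largest falls, BTC, which encodes the growth factor betacellulin, fell by 2.46 (SE 0.32, limma adjusted p = 2e-10, lower in 36 of 38 patients), from 1.94 ± 1.55 log2 CPM in NL (SD, n = 39) to -0.54 ± 1.69 in LS skin (SD, n = 40). In all, 3233 genes rose and 6463 fell, 9696 of 23582 tested, and 452 of those that rose and 480 of those that fell changed at least 2-fold.

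The keratinocyte lists fixed in advance rose together. Of 28 genes that keratinocytes induce in response to IL-17, 22 rose and none fell, also when adjusted over the list alone, and the mean of the list rose by 1.80 (95% bootstrap interval 1.41 to 2.20), in 34 of 38 patients. Besides IL36A, these were led by antimicrobial and alarmin genes: S100A7A rose by 3.20 (SE 0.49), S100A8 by 2.88 (SE 0.40), S100A9 by 2.83 (SE 0.38), PI3 by 2.68 (SE 0.41), S100A7 by 2.23 (SE 0.33) and LCN2 by 1.29 (SE 0.24). S100A8 rose from 7.11 ± 2.01 log2 CPM in NL (SD, n = 39) to 10.06 ± 2.10 in LS skin (SD, n = 40). The beta-defensin gene DEFB4A rose by 3.11 (SE 0.44), with reads that its near-identical copy DEFB4B may share. At the low end of the list, SAA1 was at -0.34 (SE 0.32, limma adjusted p = 0.41) and CXCL5 at 0.03 (SE 0.35, limma adjusted p = 0.96). All 5 keratins of epidermal hyperplasia rose, also when adjusted over the list alone, with KRT16 up by 2.75 (SE 0.36) and KRT17 by 1.16 (SE 0.30), and the list mean rose by 2.41 (1.73 to 3.06). Reads of the KRT6 genes and of KRT16 with its pseudogenes, such as KRT16P3 (log2 2.93, SE 0.35), could not be fully told apart. Of the 5 late cornified envelope 3 genes, which are induced in injured epidermis, 4 rose (5 adjusted over the list alone), among them LCE3A by 3.02 (SE 0.42) and LCE3E by 2.20 (SE 0.25). Cell cycle genes moved less: 15 of 16 rose (16 adjusted over the list alone), with RRM2 up by 0.92 (SE 0.16) and MKI67 by 0.70 (SE 0.13), and PCNA was at 0.19 (SE 0.09, limma adjusted p = 0.072), passing with array weights (0.028), quantile normalization (0.032), trimmed-mean scaling (0.013) and the library median as a covariate (0.016). The call for the proliferation list by camera, a test of a list against all other genes, was lost with an estimated correlation (adjusted p = 0.12).

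T cell and cytokine genes rose in lesional skin. All 14 T cell genes rose, also when adjusted over the list alone, with GZMB, a cytotoxic granule protease, up by 2.01 (SE 0.26), IL2RA by 1.68 (SE 0.20) and CD8A by 0.82 (SE 0.18). All 22 Th1 and interferon genes rose, also when adjusted over the list alone, including CXCL10 by 1.57 (SE 0.38), IDO1 by 1.55 (SE 0.23), MX1 by 1.13 (SE 0.18) and, at the low end, IFIT1 by 0.47 (SE 0.16). On the Th2 axis, the type 2 cytokines, receptors and chemokines that characterize atopic dermatitis, 19 of 26 genes rose and 1 fell (21 and 1 adjusted over the list alone). IL13 was 3.11-fold higher (log2 1.64, SE 0.29, limma adjusted p = 2e-06) and IL4R, a receptor subunit shared by IL-4 and IL-13, 2.14-fold higher (log2 1.10, SE 0.11, limma adjusted p = 5.5e-14). The chemokine genes CCL18, CCL17 and CCL22 rose by 1.82 (SE 0.29), 1.67 (SE 0.34) and 1.37 (SE 0.23), and the TSLP receptor gene CRLF2 by 1.72 (SE 0.21). The member that fell was GATA3, a transcription factor of Th2 cells that keratinocytes also express, at -0.48 (SE 0.12), and CCL26 was at 0.50 (SE 0.22, limma adjusted p = 0.059). Of 15 Th17 cytokine and receptor genes, 8 rose and 3 fell, also when adjusted over the list alone: IL12B rose by 1.33 (SE 0.30), IL26 by 1.29 (SE 0.31) and IL23A, a subunit of IL-23, by 0.51 (SE 0.11). The camera call for that list was lost with an estimated correlation (adjusted p = 0.19). Of 11 Th22 and IL-20 family genes, 5 rose and 1 fell, also when adjusted over the list alone, with IL22 up by 1.90 (SE 0.40) and the receptor gene IL20RA at -0.72 (SE 0.11). The camera calls for the IL-17-responsive (adjusted p = 0.012), late cornified envelope 3 (adjusted p = 0.012), T cell, Th1 and Th2 (adjusted p = 0.013 each) and hyperplasia keratin, dendritic cell and Th22 lists (adjusted p = 0.029 each) held with an estimated correlation.

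IL17A itself, the target of the drug, was near the detection floor and is given only as detection. No IL17A read was seen in 27 of 40 LS BL and 34 of 39 NL BL libraries, and no IL17F read in 19 of 40 and 27 of 39. In the secukinumab arm, 21 of 26 LS BL, 12 of 22 LS W4 and 10 of 18 LS W16 libraries had no IL17A read, against 6 of 14, 8 of 13 and 6 of 9 in the placebo arm; these shares were not tested.

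Genes of the upper epidermis moved both ways. Of 30 cornified envelope and barrier genes, 6 rose and 8 fell, also when adjusted over the list alone. HRNR rose by 1.34 (SE 0.36) and IVL by 1.33 (SE 0.21), while LCE5A fell by 1.93 (SE 0.34), KRT77 by 1.39 (SE 0.21) and LOR, which encodes the envelope protein loricrin, by 0.90 (SE 0.22). FLG, which encodes filaggrin and carries loss-of-function alleles in part of the population, was at -0.08 (SE 0.24, limma adjusted p = 0.82), and at 0.01 with the library median as a covariate. The mean of the list was at -0.23 (-0.47 to 0.02). Of 26 genes of epidermal and sebaceous lipid synthesis, 17 fell and 4 rose, also when adjusted over the list alone, and the list mean fell by 0.83 (camera adjusted p = 0.43 with an estimated correlation). ALOX12B, at 0.60 (SE 0.12), was among those that rose. Those that fell included acyltransferase genes of sebum-type lipids: DGAT2L6 fell by 2.56 (SE 0.72), AWAT2 by 2.49 (SE 0.65) and AWAT1 by 2.32 (SE 0.68).

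Markers of other structures in the biopsy fell in lesional skin. Of 11 sebaceous gland genes 9 fell (10 adjusted over the list alone), and 9 of 9 adipocyte, 8 of 8 eccrine sweat gland and 4 of 4 erythrocyte genes fell, these also when adjusted over the list alone. The list means fell by 1.49, 1.31, 1.16 and 1.41, in 29, 32, 35 and 27 of 38 patients, and the camera calls were lost with an estimated correlation (adjusted p = 0.38, 0.37, 0.37 and 0.37). LEP, the leptin gene, fell by 1.79 (SE 0.49), PLIN1 by 1.40 (SE 0.39), PIP, a product of sweat glands, by 1.49 (SE 0.38), SCGB1D2 by 1.39 (SE 0.31) and HBB by 1.51 (SE 0.39). Of 7 skeletal muscle genes, 4 fell, TNNT3 by 0.93 (SE 0.17), with 1 rising as well when adjusted over the list alone, and the list mean fell by 0.51 (camera adjusted p = 0.20 with the preset and 0.38 with an estimated correlation). Of 14 hair follicle genes only KRT31 fell, by 1.14 (SE 0.28), also when adjusted over the list alone. The other genes with the largest falls were AADACL3 at -3.43 (SE 0.80), UGT3A2 at -2.82 (SE 0.43), PM20D1 at -2.72 (SE 0.68), LOC100996338 and CYP1A2 both at -2.29 (SE 0.44 and 0.46) and THRSP at -2.28 (SE 0.51). LOC100996338 and CYP1A2 had medians of 2 and 1 reads in LS and 16 and 10 in NL libraries.

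Among myeloid and stromal lists, only dendritic cells held in camera with an estimated correlation. Of 13 dendritic cell genes, 11 rose, also when adjusted over the list alone, among them CD1B by 1.98 (SE 0.33) and CD80 by 1.68 (SE 0.27), whereas CD207, the Langerhans cell gene langerin, was at -0.07 (SE 0.21, limma adjusted p = 0.81), and at 0.01 with the library median as a covariate. Of 10 macrophage genes 8 rose, also when adjusted over the list alone, with MRC1 up by 0.93 (SE 0.21) and C1QC by 0.81 (SE 0.16) (camera adjusted p = 0.20 with an estimated correlation). Of 11 fibroblast and matrix genes 8 rose, also when adjusted over the list alone, with THY1 up by 1.20 (SE 0.17) and COL3A1 by 0.94 (SE 0.20) (camera adjusted p = 0.19 with an estimated correlation). Of 9 neutrophil genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with MMP9 up by 1.25 (SE 0.19) and AQP9 down at -1.14 (SE 0.25), and with a camera adjusted p = 0.20 with an estimated correlation. Of 9 B and plasma cell genes 2 rose (1 adjusted over the list alone), MZB1 by 1.5 (SE 0.30), with a camera adjusted p = 0.38 with an estimated correlation. Of 8 mast cell genes 2 rose, HDC by 0.65 (SE 0.15). Of 8 melanocyte genes 2 rose and 2 fell, with TYRP1 at 0.61 (SE 0.17) and SOX10 at -0.60 (SE 0.12). Of 9 endothelial genes 1 rose and 2 fell, with SELE at 1.49 (SE 0.25) and CLDN5 at -0.67 (SE 0.14). Of 11 immediate-early and heat-shock genes, a sign of tissue handling, 2 rose and 2 fell, with JUNB at 0.39 (SE 0.12) and HSPA1B at -0.30 (SE 0.08), and the list mean was at -0.01 (-0.21 to 0.16). The counts of these last 4 lists were the same when adjusted over the list alone.

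Over the 26 lists, a sign-flip permutation test of each patient's difference called 14 lists higher and 6 lower at baseline, the smallest p it can give being 1e-05 (adjusted 2.2e-05). The remaining named genes with the largest rises were MMP1 at 3.11 (SE 0.54), the protease inhibitor gene SERPINB4 at 2.97 (SE 0.44) and SPRR2A at 2.83 (SE 0.40). IL36A lies on chromosome 2 at 113005461 to 113008044, KRT6C on chromosome 12 at 52468516 to 52473785, S100A8 on chromosome 1 at 153390032 to 153391188, IL13 on chromosome 5 at 132656263 to 132661110 and BTC on chromosome 4 at 74744759 to 74794686 (GRCh38), all protein-coding genes counted as wholes. Lower genes made up 66.7% of the calls on the deposited scale, but under quantile normalization the calls were 4322 higher and 4611 lower, and under trimmed-mean scaling 4246 higher and 4977 lower. By arm, 8229 genes were called in the secukinumab and 408 in the placebo arm, the placebo count falling to 178 without 4 libraries of doubtful identity and to 0 with the patient block ignored. The arms' difference called 0 genes by limma or with voom weights, with 549 at an unadjusted p under 0.05.

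**Figure D1:**
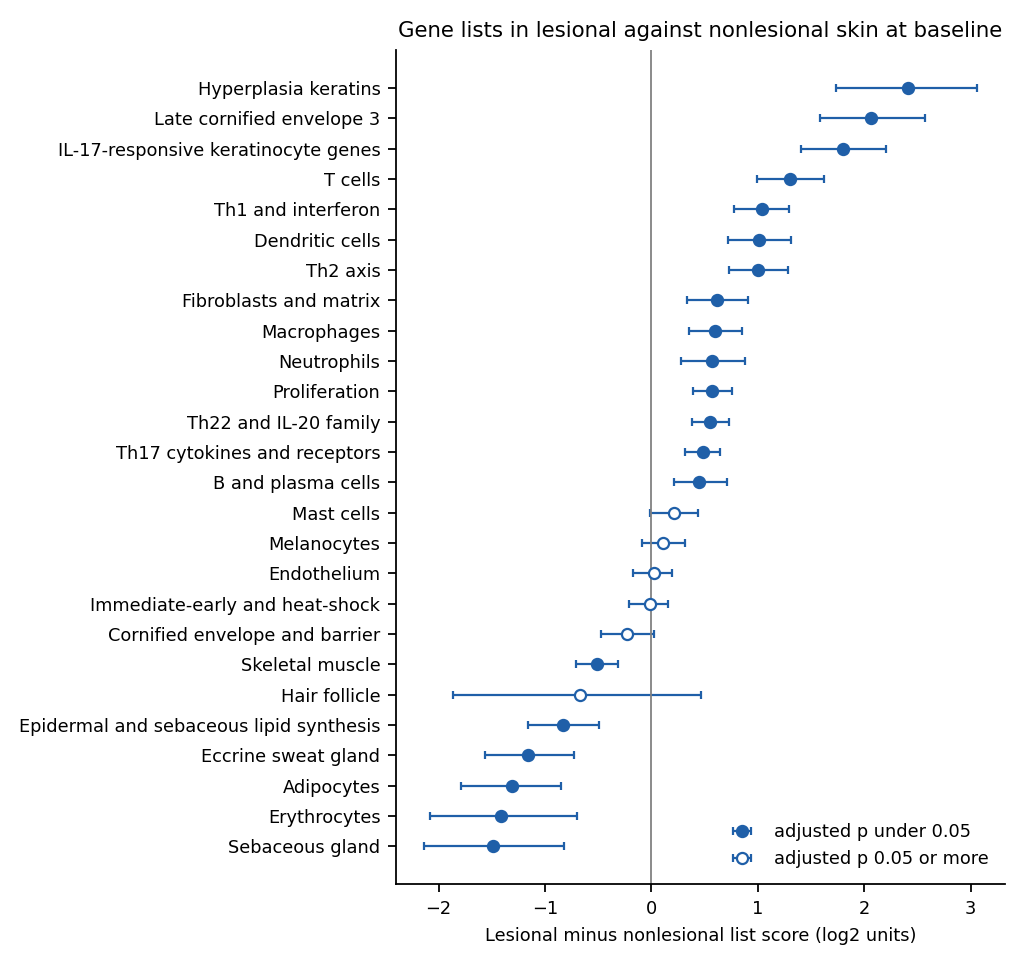
Mean lesional minus nonlesional list score per patient at baseline for 26 gene lists (x axis, log2 units; 38 patients), with 95% bootstrap intervals; filled points have an adjusted permutation p under 0.05. Hyperplasia keratins (2.41) and late cornified envelope 3 genes (2.06) lie highest and sebaceous gland genes (-1.49) lowest.

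**Figure D2:**
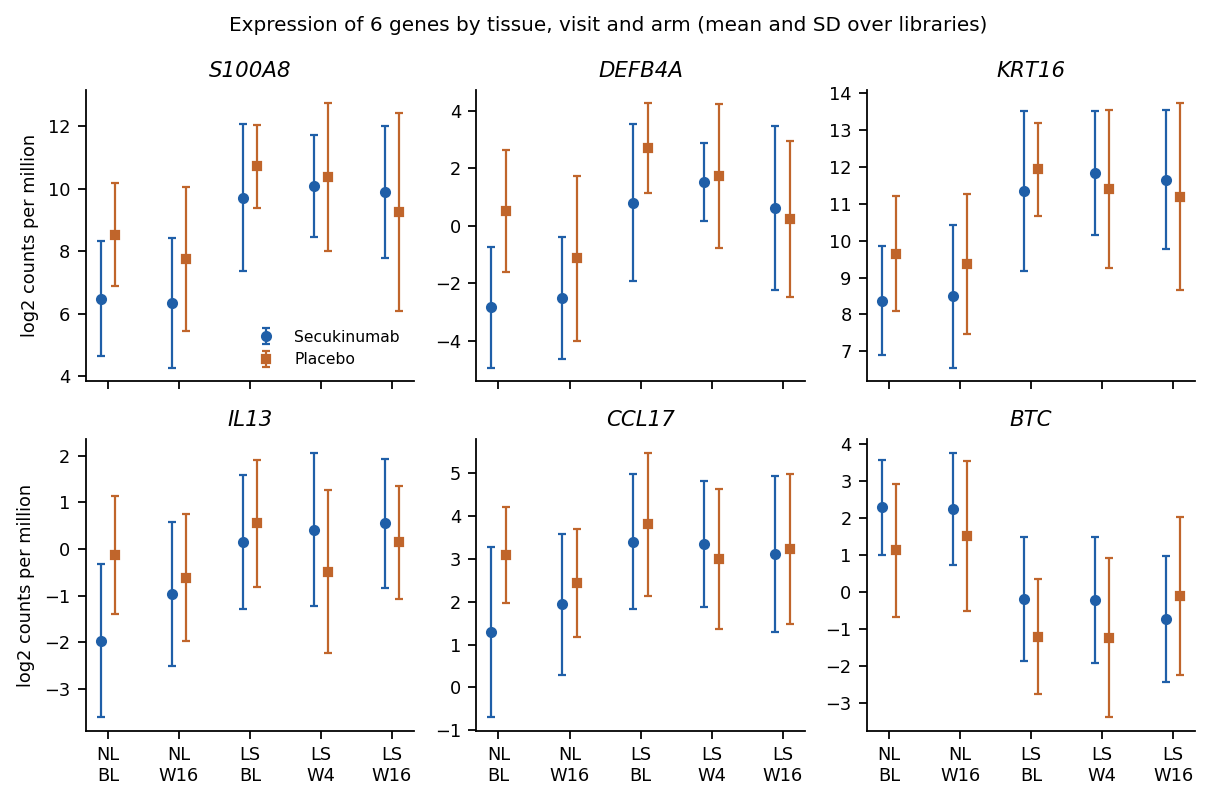
Levels of 6 genes (y axes, log2 CPM) by tissue, visit and arm, as mean and SD over libraries. S100A8, DEFB4A, KRT16, IL13 and CCL17 were higher and BTC lower in lesional than in nonlesional skin at baseline, and in NL skin at baseline the mean of each of those 5 was higher in the placebo than in the secukinumab arm.

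After 4 weeks, no gene passed over all genes and no list score, taken as the mean of the deposited values, passed in either arm. With z-scores the lipid synthesis list passed on secukinumab, as it did under quantile normalization and, with sebaceous gland and fibroblast genes, under trimmed-mean scaling. On secukinumab (22 patients), the mean of the IL-17-responsive list changed by 0.29 (-0.36 to 0.95), the Th2 list by 0.07 (-0.38 to 0.48) and the hyperplasia keratins by 0.43 (-0.44 to 1.45), and on placebo (13 patients) by -0.33 (-1.27 to 0.41), -0.31 (-0.85 to 0.11) and -0.10 (-1.51 to 1.24). In the same order these lists were higher in 12, 14 and 10 of 22 secukinumab patients and in 9, 6 and 8 of 13 placebo patients. Most placebo patients thus went against the negative means of the IL-17-responsive list and the hyperplasia keratins. The difference between the arms, secukinumab minus placebo, was 0.61 (-0.39 to 1.73, permutation p = 0.29) for the IL-17-responsive list. For single genes it was 1.69 (SE 0.94) for DEFB4A, 0.77 (SE 0.85) for S100A8, 0.74 (SE 0.71) for S100A7, 0.50 (SE 0.52) for LCN2, 1.02 (SE 0.77) for KRT16, -0.37 (SE 0.71) for CCL20 and -0.02 (SE 0.27) for MKI67. Among cytokine and chemokine genes it was 2.29 (SE 1.02) for IL19, 1.55 (SE 0.85) for IL22, 1.29 (SE 0.63) for IL13 and 0.70 (SE 0.73) for CCL17, each with a limma adjusted p = 1.0.

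Limma called 0 genes for the change to week 4 on secukinumab, on placebo and for the difference between the arms (0 with voom weights), with 876, 565 and 449 genes at an unadjusted p under 0.05. The genes with the smallest p, none of which passed (limma adjusted p = 1.0), were on secukinumab DCSTAMP (1.27, SE 0.34), ELN (0.79, SE 0.22), TMEM150B (0.91, SE 0.26), the sebocyte melanocortin receptor gene MC5R (-1.74, SE 0.46), HFE2 (-0.89, SE 0.25) and RBM3 (-0.17, SE 0.05). On placebo they were LOC101927810 (1.64, SE 0.46), LINC00535 (1.54, SE 0.44), LOC102723921 (1.25, SE 0.37), NPM2 (-0.88, SE 0.21), RTN4RL2 (-0.57, SE 0.15) and SNORA2A (-1.50, SE 0.41). For the difference they were NPM2 (1.07, SE 0.26), ZNRF2P1 (1.71, SE 0.52), ST6GAL1 (0.74, SE 0.23), MYT1L (-1.92, SE 0.49), LOC102723921 (-1.60, SE 0.46) and RP11-450K4.1 (-1.45, SE 0.44). Of the 26 list scores 0 passed in either arm or between the arms, with 4, 3 and 1 at an unadjusted p under 0.05. Camera with the preset correlation of 0.01 did call lists in each arm and between the arms, which these score tests did not. The nearest on secukinumab were lipid synthesis at -0.67 (16 of 22 patients lower, adjusted p = 0.058), fibroblasts and matrix at 0.46 (16 of 22 higher, adjusted p = 0.058) and sebaceous gland at -1.24 (14 of 22 lower, adjusted p = 0.066), by permutation. Adjusted over the list alone, 5 of 11 fibroblast genes rose and 1 of 11 sebaceous genes fell on secukinumab, and 3 of 8 melanocyte genes fell on placebo. The melanocyte list gave the smallest p between the arms, at 0.50 (0.13 to 0.95, permutation p = 0.0134, adjusted p = 0.35). On simulated data, the test of the difference between the arms recovered 42% of genes changed 1.5-fold, 68% of those changed 2-fold and 96% of those changed 4-fold, with 17 false calls. The changed genes were random ones with a mean above 0 log2 CPM. These shares do not hold for variable genes such as S100A8, DEFB4A and KRT16, whose SEs above are near the size of a 2-fold change.

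At week 16 again no gene passed over all genes and no list score passed in either arm. On secukinumab (17 patients with both biopsies) the IL-17-responsive list changed by -0.01 (-0.79 to 0.71), the Th2 list by 0.04 (-0.39 to 0.43), T cells by 0.08 (-0.40 to 0.50) and hyperplasia keratins by -0.09 (-1.10 to 0.85). On placebo (9 patients) the same lists changed by -0.73 (-2.07 to 0.64), -0.08 (-0.62 to 0.41), 0.04 (-0.48 to 0.50) and -0.37 (-2.59 to 1.67). The arms differed by 0.73 for the IL-17-responsive list (-0.84 to 2.25, exact permutation p = 0.347). Between the arms, DEFB4A differed by 1.95 (SE 1.05), S100A8 by 1.37 (SE 0.94), S100A7 by 0.84 (SE 0.78), LCN2 by 0.83 (SE 0.58), KRT16 by 0.86 (SE 0.85), MKI67 by 0.47 (SE 0.30) and CCL20 by -0.33 (SE 0.79). IL19 differed by 3.12 (SE 1.13), IL22 by 0.87 (SE 0.94), IL13 by 0.68 (SE 0.69) and CCL17 by 0.34 (SE 0.81), with limma adjusted p between 0.59 and 0.89 for these 11 genes. IL19 had a median of 6 reads in LS BL libraries.

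Limma called 0 genes on secukinumab, on placebo and between the arms (0 with voom weights), with 971, 1147 and 1645 at an unadjusted p under 0.05. None of the genes with the smallest p passed. On secukinumab (limma adjusted p = 0.92) they were LRRC71 (1.05, SE 0.27), MIR3674 (1.18, SE 0.33), IL3 (0.82, SE 0.24), FLJ45139 (-1.23, SE 0.33), TYRO3P (-1.0, SE 0.28) and SLC16A12 (-0.85, SE 0.25). On placebo they were KCNJ3 (2.30, SE 0.52, limma adjusted p = 0.40) and, with a limma adjusted p = 0.79, LOC101927159 (1.18, SE 0.29), KCTD6 (0.49, SE 0.13), MIR4653 (-0.93, SE 0.26), SLC35G6 (-1.59, SE 0.47) and SLC5A2 (-1.32, SE 0.45). For the difference (limma adjusted p = 0.59) they were MIR4653 (1.08, SE 0.32), TNFAIP8L1 (0.53, SE 0.16), GIMAP5 (1.51, SE 0.48), LOC101927159 (-1.39, SE 0.36), LOC101930232 (-2.17, SE 0.57) and KCTD6 (-0.61, SE 0.16). LOC101927159 passed with array weights, at 1.69 on placebo (limma adjusted p = 0.0013) and -1.95 between the arms (limma adjusted p = 0.0044). Of the 26 list scores 0 passed, with 2 on secukinumab, 3 on placebo and 1 between the arms at an unadjusted p under 0.05. B and plasma cell genes on secukinumab were at 0.63 (13 of 17 patients higher, adjusted p = 0.33), with 1 of 9 members rising when adjusted over the list alone. Skeletal muscle on placebo was at 0.57 (9 of 9 higher, adjusted p = 0.10), and lipid synthesis between the arms at -0.73 (exact permutation p = 0.0387, adjusted p = 0.56). On simulated data, the test between the arms recovered 30% of genes changed 1.5-fold, 74% of those changed 2-fold and 96% of those changed 4-fold, with 8 false calls. Here too the changed genes were random ones with a mean above 0 log2 CPM. For S100A8, DEFB4A and KRT16, with SEs above near the size of a 2-fold change, these shares do not hold.

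**Figure D3:**
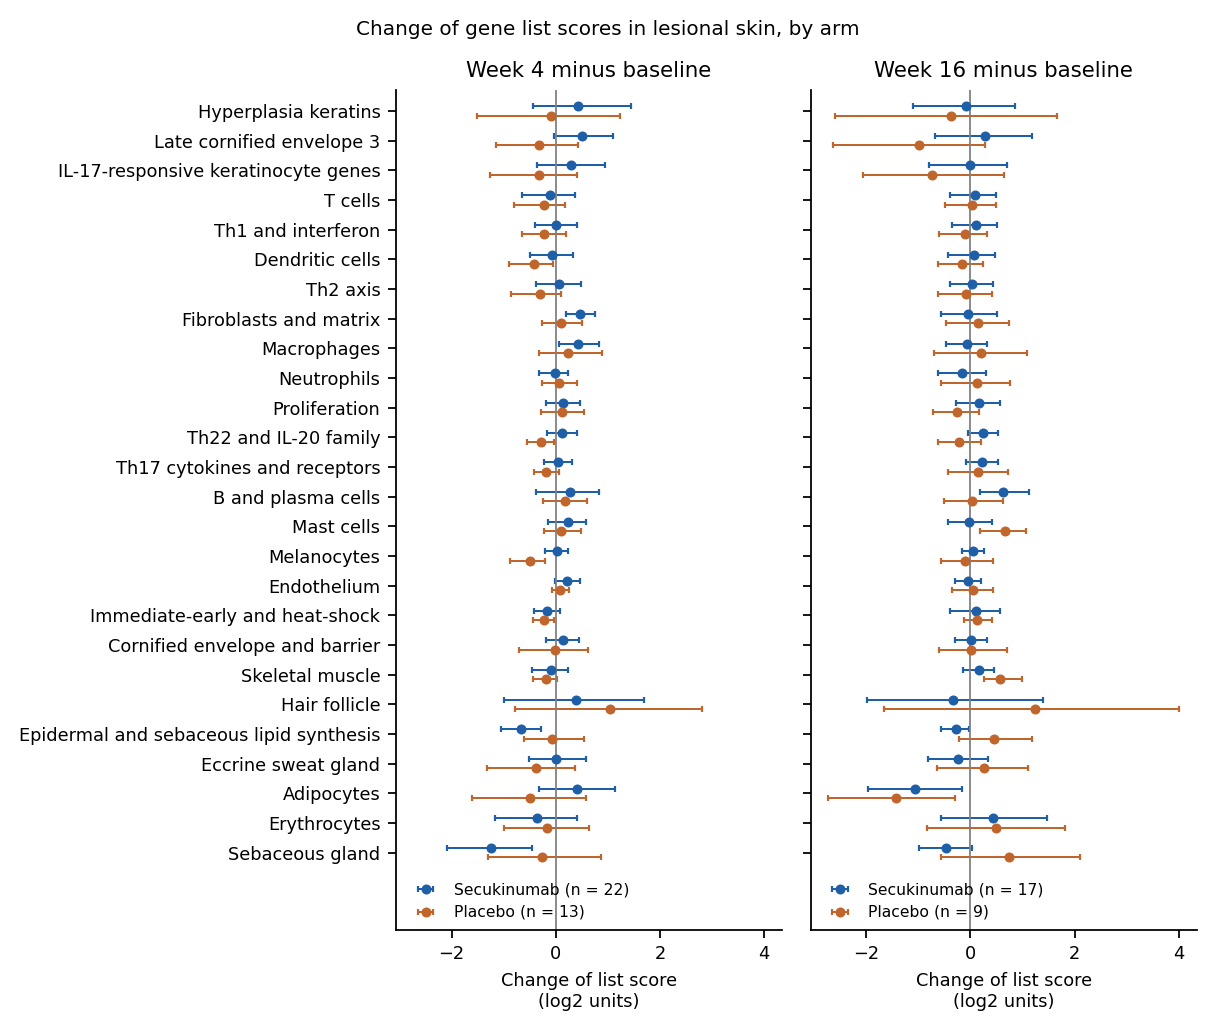
Change of 26 list scores in lesional skin from baseline to week 4 (left; 22 and 13 patients) and week 16 (right; 17 and 9 patients), in log2 units, as means with 95% bootstrap intervals for secukinumab and placebo. None of the changes, and none of the differences between the arms, passed the adjusted permutation tests.

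The lesional genes were also summed into one measure. The lesional score was the mean of the 452 genes that rose at least 2-fold in lesional skin at baseline minus the mean of the 480 that fell at least 2-fold, chosen on these samples. At baseline it was 2.76 higher in lesional skin (2.33 to 3.16; 37 of 38 patients), a gap of 2.96 in the secukinumab and 2.32 in the placebo arm. On secukinumab it changed by 0.32 (-0.28 to 0.94) to week 4 and 0.18 (-0.55 to 0.87) to week 16, which is 10.8% and 6.1% of the gap, away from nonlesional skin. On placebo it changed by -0.25 (-1.12 to 0.44) and -0.57 (-1.61 to 0.45), which is -10.8% and -24.6% of the gap. The gaps came from all patients with both baseline biopsies (26 and 12). The percentages thus set the changes against gaps from a different set of patients. The score was lower in 7 of 13 and 5 of 9 placebo patients, and higher in 11 of 22 and 11 of 17 secukinumab patients. In placebo LS skin at week 4, 1 library lay at -0.37 with the next at 2.31, so the mean fall there leans on 1 patient. Genes chosen on the baseline libraries widen the gap and build in some fall of LS skin. With genes chosen in other patients the gaps were 2.42 and 1.82, and the changes 0.35 (-0.17 to 0.89) and 0.16 (-0.44 to 0.74) on secukinumab and -0.15 (-0.98 to 0.49) and -0.48 (-1.45 to 0.45) on placebo. The arms differed by 0.57 at week 4 (-0.36 to 1.61, permutation p = 0.283; 0.24 without the libraries of doubtful identity, p = 0.615) and by 0.75 at week 16 (-0.50 to 1.99, exact permutation p = 0.266). The bounds of -0.36 and -0.50 limit the mean improvement on secukinumab over placebo that these intervals leave open. They rest on 13 and 9 placebo patients and on changes not adjusted for baseline. The mean of lesional skin started higher on placebo (secukinumab minus placebo -0.58, permutation p = 0.16), a difference that did not pass. It was -0.41 with genes chosen in other patients (permutation p = 0.264) and -0.19 with no fold limit (permutation p = 0.282). A higher start on placebo can build in a larger fall there. The bounds may therefore understate an improvement on secukinumab.

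**Figure D4:**
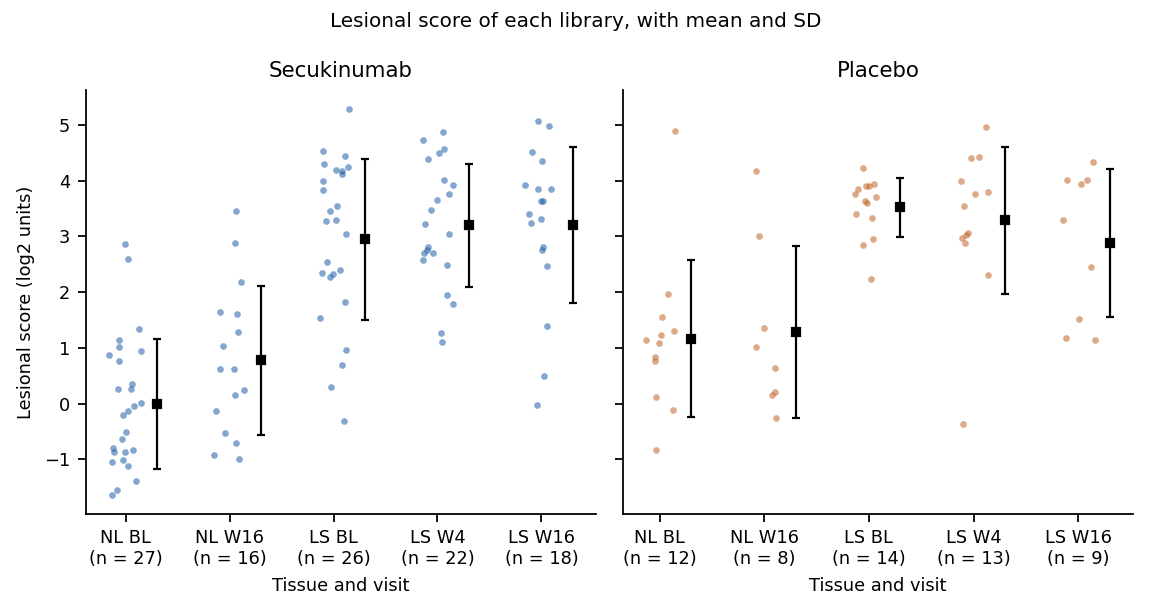
Lesional score of each library (y axis, log2 units) by tissue and visit in the secukinumab (left) and placebo (right) arms, with the group mean and SD as a square and bar. LS groups had means between 2.88 and 3.53 and NL groups between -0.00 and 1.29.

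It was asked whether patients with a higher baseline IL-17-responsive score in lesional skin changed more. The slope of the change of the lesional score on that baseline score was -0.66 on secukinumab and -0.92 on placebo at week 4, a difference of 0.26 (permutation p = 0.587). At week 16 the slopes were -0.81 and -0.88, a difference of 0.07 (permutation p = 0.899). A change contains its baseline value, so negative slopes arise in both arms without treatment, and only their difference bears on the question.

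In nonlesional skin no gene was called for the change from baseline to week 16. The lesional score was tested there after the other results were known. It rose on secukinumab by 0.64 (0.20 to 1.09; 12 of 16 patients higher; exact permutation p = 0.0166), with p between 0.0119 and 0.0354 over its alternatives. Its genes were chosen partly on the same NL BL libraries, which builds in some rise. With genes chosen in other patients the rise was 0.47 (0.10 to 0.86; 11 of 16 higher; exact permutation p = 0.0354). On placebo it changed by 0.61 (-0.48 to 2.04; 3 of 8 higher; exact permutation p = 0.516). The arms differed by 0.02 (exact permutation p = 0.969), so the rise is not shown to belong to the drug. Most placebo patients did not rise, and placebo NL W16 libraries lay at 4.17 and 3.01 with the next at 1.35. The placebo mean may therefore lean on few patients, and the arms are not shown to be alike. Of the 26 list scores 0 passed on secukinumab, on placebo or between the arms, with 0, 3 and 1 at an unadjusted p under 0.05. On secukinumab (27 NL BL and 16 NL W16 libraries) the smallest p were those of SNORD33 (1.19, SE 0.27), RPL13P5 (0.40, SE 0.09) and LOC101928828 (-1.05, SE 0.25), each with a limma adjusted p = 0.28, LOC102724081 (-1.53, SE 0.37, limma adjusted p = 0.30), the resident T cell gene ZNF683 (1.24, SE 0.31, limma adjusted p = 0.49) and LINC00284 (-1.41, SE 0.36, limma adjusted p = 0.50). On placebo (12 and 8 libraries) they were NME8 (1.69, SE 0.40), LOC102724009 (0.93, SE 0.22), NR2E3 (1.32, SE 0.34), LOC102723361 (-2.03, SE 0.52), LOC646513 (-1.88, SE 0.49) and LOC102723798 (-1.59, SE 0.45), with limma adjusted p between 0.50 and 1.0. Between the arms they were AL592528.1 (1.53, SE 0.43), MIR6753 (1.96, SE 0.56), LOC646513 (2.08, SE 0.60), KCNAB1-AS1 (-1.68, SE 0.45), SLC17A8 (-2.79, SE 0.70, limma adjusted p = 0.97) and LOC101929918 (-2.57, SE 0.59, limma adjusted p = 0.54). Limma called 0 genes in each of the 3 tests (0 with voom weights), with 1554, 746 and 1023 at an unadjusted p under 0.05. With array weights SLC17A8 (-3.31) and LOC101929918 (-2.80) passed between the arms (limma adjusted p = 0.037 each).

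At week 16 the lesional profile was still present on secukinumab. Between 18 LS W16 and 16 NL W16 libraries, 16 patients having both, KRT6C was 19.2-fold higher in lesional than in nonlesional skin (log2 4.27, SE 0.82, limma adjusted p = 0.00026), S100A7A 14.8-fold (log2 3.89, SE 0.74, limma adjusted p = 0.00023) and IL36A 12.8-fold (log2 3.67, SE 0.66, limma adjusted p = 9.4e-05). Of the IL-17-responsive genes 18 of 28 rose and 0 fell (20 adjusted over the list alone), of hyperplasia keratins 5 of 5 and of late cornified envelope 3 genes 5 of 5 (the same adjusted over the list alone), of proliferation genes 14 of 16 (16), of T cell genes 12 of 14 (13), of Th1 and interferon genes 17 of 22 (20) and of Th2 genes 13 of 26, with 1 fall (17 and 1). The camera calls for these 7 lists held with an estimated correlation (adjusted p = 0.0036, 0.013, 0.0033, 0.013, 0.040, 0.013 and 0.031). Also among the largest rises were MMP1 (3.82, SE 0.83), S100A8 (3.48, SE 0.61), SERPINB4 (3.45, SE 0.67), SPRR2C (3.43, SE 0.71), KRT16P3 (3.35, SE 0.54), S100A9 (3.27, SE 0.58) and DEFB4A (3.16, SE 0.67). BTC fell by 2.92 (SE 0.48), in 16 of 16 patients, followed by C10orf129 (-2.91, SE 0.85), SOHLH1 (-2.69, SE 0.49), SEC14L6 (-2.64, SE 0.83), PNPLA5 (-2.42, SE 0.77), LEP (-2.40, SE 0.75), LOC731779 (-2.35, SE 0.45), LOC102723971 (-2.30, SE 0.52), THRSP (-2.27, SE 0.77) and ELOVL3 (-2.24, SE 0.77). In all, 1445 genes rose and 2596 fell (4041). The count was 1298 with the patient block ignored, 2179 with the patients who had all 5 biopsies and 6607 with array weights. The split was 2090 higher and 1645 lower under quantile normalization, and 1994 higher and 1605 lower under trimmed-mean scaling.

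Between 9 LS W16 and 8 NL W16 libraries of the placebo arm, 8 patients having both, limma called 0 genes (0 with voom weights), with 2223 at an unadjusted p under 0.05. The smallest p were those of RP11-475O6.1-2 (-2.34, SE 0.49, limma adjusted p = 0.11; 0.036 with array weights, at -2.50) and, with a limma adjusted p = 0.48, LOC101929866 (2.23, SE 0.56), LOC102724895 (1.91, SE 0.49), LOC646513 (1.87, SE 0.52), AC012314.8 (-0.85, SE 0.21) and ENTPD3-AS1 (-0.84, SE 0.21). Adjusted over the list alone, 3 of 5 late cornified envelope 3 genes and 1 of 22 Th1 and interferon genes rose, and 0 passed over all genes. The difference between the arms in the lesional against nonlesional contrast, added after the arms' counts were seen, called 0 genes by limma (0 with voom weights), with 454 at an unadjusted p under 0.05. The lesional score gave a gap of 2.63 on secukinumab and 1.64 on placebo, a difference of 0.98 (0.10 to 1.83, exact permutation p = 0.0506). Before treatment the gaps were already 2.96 and 2.32, a difference of 0.64 (-0.21 to 1.59, permutation p = 0.17).

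Before treatment, no gene and no list score passed between the arms in lesional skin. The list scores were added after the other results were known. Of these 0 of 26 passed and 1 had an unadjusted p under 0.05, hair follicle genes at 2.04 (0.49 to 3.43, permutation p = 0.0103, adjusted p = 0.27). The IL-17-responsive list was at -0.71 (-1.40 to 0.00, permutation p = 0.0889, adjusted p = 0.58) and the lesional score at -0.58 (-1.19 to 0.03, permutation p = 0.16). A lower start on secukinumab is not excluded. Limma called 0 genes between 26 secukinumab and 14 placebo LS BL libraries (0 with voom weights), with 522 at an unadjusted p under 0.05. The smallest p were those of ITIH6 (2.14, SE 0.47, limma adjusted p = 0.23), SNHG5 (0.92, SE 0.22, limma adjusted p = 0.54), the mast cell tryptase gene TPSD1 (1.96, SE 0.59), PRKRIP1 (-0.98, SE 0.27), LOC102723840 (-1.36, SE 0.40) and ARSF (-1.08, SE 0.32), the last 4 with a limma adjusted p = 1.0.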

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

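The tests of the sample-sheet set and of the arithmetic effect of the most abundant genes were chosen after the result they bear on was seen, as was the difference between the arms at week 16; the tests on regrouped samples were written after the real counts were known.

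Among 62 sets of values in groups of 8 to 10 libraries, 4 had a library far from the others, where about 1 in 20 is reached by chance. In placebo LS skin at week 16, the highest library had a B and plasma cell score of 3.27 log2 CPM, with the next at 0.59, and the highest library had an eccrine sweat gland score of 8.03, with the next at 5.53. In placebo NL skin at week 16, the highest library had a Th2 score of 3.00, with the next at 1.79, and the deepest library had 42.33 M reads, with the next at 35.02 M.

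The lean of the baseline calls towards lower genes (6463 of 9696, 66.7%) moved with the scaling. Lower genes made up 54.0% of the calls under trimmed-mean scaling and 51.6% under quantile normalization. Both methods centre the libraries on each other, which pulls the share towards even whatever the source. They therefore cannot tell the scale of the libraries from biology as the source of the excess. The direction of genes with small changes stays open. The tables argue against genes near the detection floor as the whole source, since 61.9% of the 6354 called genes with a mean of at least 1 log2 CPM were lower. That share is below the 66.7% of all calls, so genes of lower level leaned more to lower calls and hold part of the excess. Without the 631 called genes that follow the sebaceous score, 64.4% were lower. Those genes were too few to be the whole source, and leaving them out could not have brought the share near even. Whether fewer sebaceous structures in the lesional biopsies contribute more widely is therefore not decided. A broad lowering of transcripts in lesional skin is the biological alternative, and it was not tested separately from the scaling.

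The absence of calls between lesional and nonlesional skin at week 16 on placebo may come from the small number of patients. When 8 of the 16 secukinumab patients were drawn 100 times, 9 draws called as few genes, with a median of 292 and quartiles of 25.5 and 798.75. Leaving out libraries of outlying median, 2 of them from placebo LS skin at week 16, still gave 0 calls, but with fewer patients left than in those draws this does not decide whether these libraries matter. A smaller lesional difference on placebo remains open: the lesional score differed between the arms by 0.98 (exact permutation p = 0.0506, and 0.0451 to 0.147 over its alternatives), and the design has too few placebo patients to settle it. Before treatment the gap already differed by 0.64 in the same direction (26 and 12 patients, permutation p = 0.17). The week-16 difference is therefore not shown to have arisen on treatment.

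Libraries differed in their median value, from 1.23 to 3.07 log2 CPM, and the first principal component (13.3% of the variance) followed that median (r = 0.74 in size). The median was lower where the 10 most abundant genes took more of the reads (Pearson r = -0.72, Spearman rho = -0.68, permutation p = 1e-05 each, the smallest possible). These permutations treated all libraries as independent, although each patient gave several. The Pearson r was -0.71 without the 2 farthest libraries, and from -0.81 to -0.67 within the 3 sample-sheet sets. Taking those genes out of the totals left 89.0% of the SD of the median, so their reads alone, as arithmetic, do not account for it, and the set explained only 3.9% of its variance. Across 19923 genes, which are not independent replicates, the correlation of a gene with the library median followed its GC content (rho = -0.60) and transcript length (rho = 0.39). RNA quality or library preparation is a candidate cause, and no biological explanation was tested.

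Chance can be excluded for the calls between lesional and nonlesional skin at baseline (9696, the highest of the other splits being 3) and at week 16 on secukinumab (4041 against 2), where 1 of 100 splits, the real one, gave as many; the others swapped the tissues at random within patients, so all pairs stayed parted. For the comparisons with 0 calls, 100 of 100 splits gave as many by construction, which says nothing about chance. The highest other counts were 1 for lesional against nonlesional skin at week 16 on placebo, 1, 1 and 1 for the change to week 4 on secukinumab, on placebo and between the arms, 2, 2198 and 829 for the change to week 16, 191, 3 and 3441 for that of nonlesional skin, and 12 and 2689 between the arms at baseline in lesional and nonlesional skin. The visits were shuffled within patients and the arms over patients. Splits calling over 100 genes were rare, 1 to 3 of 100 in the 5 comparisons that had any, and what they follow was not tested.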

How the results depend on the processing

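Over 25 results, 227 of 251 values under alternatives were kept. Counts of genes or lists were kept if equal, as where 0 stayed 0, or within 1.5 times, whatever their direction. Differences of scores and slopes were kept if their sign and their side of the 0.05 threshold stayed. The week-16 count on secukinumab was kept under quantile normalization and trimmed-mean scaling, although its majority turned from lower to higher genes. At baseline 7400 genes were called with no replicate block and 9921 with the patient as a fixed effect, against 9696. The block changed a count over 1.5 times in 1 planned comparison: with no replicate block, lesional against nonlesional skin at week 16 on secukinumab had 1298 calls in place of 4041. The other changes of that count were 6607 with array weights and 2179 with only the patients with all 5 biopsies, and at least 2-fold there were 779 (932 at baseline). Array weights added 1 gene each for the change to week 16 on placebo, the arms' difference in it and week-16 lesional against nonlesional skin on placebo, and 2 for the nonlesional difference, and PCNA passed with them at baseline. Of the list scores, 8 of 20 baseline calls held in camera with an estimated correlation, whose preset correlation called 9 and 11 lists at week 4 and 6 and 6 at week 16 (secukinumab, placebo), and 11 and 7 between the arms, where the score tests called 0. The lists called at week 4 on secukinumab were 1 with z-scores and 1 under quantile normalization (lipid synthesis, lower) and 3 under trimmed-mean scaling (also sebaceous gland, lower, and fibroblasts, higher), and 1 list passed between the arms with the patients with all 5 biopsies. The difference in the week-16 gap of the lesional score passed with cross-fitted genes (0.85, exact permutation p = 0.0451) and z-scores (0.62, exact permutation p = 0.0492). With cross-fitted genes the gaps were already 2.42 and 1.82 before treatment (secukinumab, placebo). With the Th2 list as baseline measure the slope differences were reversed, at -0.46 (permutation p = 0.629) and -0.75 (permutation p = 0.532). Of genes not passing, SAA1 (0.10) with all 5 biopsies, CXCL5 with array weights (-0.13) and without libraries of outlying median (-0.03), FLG and CD207 with the library median as covariate (0.01 each), and, between the arms, CCL20 (0.16 at week 4 with all 5 biopsies, 0.15 at week 16 with array weights) and MKI67 (0.14 at week 4 with all 5 biopsies) changed sign. Beyond fewer samples, the cause was not tested. Leaving out the 4 libraries of doubtful identity, chosen after the data were seen, gave 9138 calls at baseline and 4260 at week 16 on secukinumab. Not run were a setting without a filter, since the filter removed nothing, settings for counts or linear values, and the patient as a fixed effect for the arms at baseline, where it could not be fitted. Trimmed-mean scaling cannot move the lesional score. Depth limits genes of few reads, IL17A among them.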

Other observations

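The comparison of the arms in nonlesional skin at baseline was chosen after the group means were seen, the same tests in lesional skin and without the highest library later still, and the regression on baseline scores was planned.

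Before treatment, nonlesional skin of the placebo arm carried more of the lesional profile than that of the secukinumab arm. The IL-17-responsive list was 1.36 lower on secukinumab (0.36 against 1.71 log2 CPM; 27 and 12 patients; interval -1.93 to -0.82; permutation p = 2e-05, adjusted p = 0.00052). The Th22 and IL-20 family list was at -0.51 (adjusted p = 0.0031) and the Th2 axis at -0.76 (adjusted p = 0.018), 3 of 26 lists passing and 9 at an unadjusted p under 0.05. S100A8 stood at 8.53 ± 1.64 log2 CPM on placebo (SD, n = 12) and 6.48 ± 1.85 on secukinumab (SD, n = 27), DEFB4A at 0.51 ± 2.12 and -2.83 ± 2.11, and CCL17 at 3.08 ± 1.12 and 1.29 ± 1.99. By single genes limma called 0 (0 with voom weights, 1 with array weights), with 1578 at an unadjusted p under 0.05.

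The arms may therefore have started from different nonlesional skin, which would narrow the lesional gap of the placebo arm. The lesional score of nonlesional skin was 1.17 lower on secukinumab (-0.00 against 1.16, interval -2.09 to -0.33, permutation p = 0.0091). Its genes were chosen partly on these same NL BL libraries, with more weight on the secukinumab arm, which may widen the difference. The score was 1.10 lower without the libraries of doubtful identity (permutation p = 0.0188) and 1.27 lower with the means of the sample-sheet sets removed (permutation p = 0.0064). One placebo library stood at 4.90, with the next at 1.97, and without it the difference was -0.83 (27 and 11 patients; -1.44 to -0.17; p = 0.0397) and the same 3 lists passed. In the 22 patients with all 5 biopsies it was only 0.40 lower (14 and 8 patients, exact permutation p = 0.418), and of the lists only the IL-17-responsive one passed there (-1.28, exact permutation p = 0.00137, adjusted p = 0.036). In lesional skin the same tests gave 0 of 26 lists passing and a lesional score at -0.58 (-1.19 to 0.03, permutation p = 0.16), the same direction. The baseline gap between lesional and nonlesional skin differed by 0.64 between the arms (permutation p = 0.17), so the tissues are not shown to differ in this.

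It was asked whether patients whose lesions carried more IL-17-responsive transcripts improved more on secukinumab. The slopes of the change of the lesional score on that baseline score differed by 0.07 at week 16 (permutation p = 0.899) and 0.26 at week 4 (permutation p = 0.587), so no such relation was detected, and the number of patients leaves it open.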
